A study of Mus musculus with 16 samples.

How the data were processed

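Long RNA and small RNA were sequenced from 2 mouse glioma cell lines and from 3 fractions of the medium conditioned by each line, giving 16 libraries, 1 for each line, fraction and kind of RNA. Per the labels' protocols, cells of passage 8 to 12 grew in 10% FBS, were held in 0.1% FBS for 16 h, and conditioned fresh medium for 24 h. Medium was spun at 300 g for 10 min and at 2000 g for 15 min, and passed through filters of 2 and 0.8 µm. Small microvesicles were then held on a 0.22 µm filter, exosomes on a 0.02 µm filter, and RNPs on a 3 kDa column, per the labels' protocols. Long RNA libraries were made after rRNA depletion with SMARTer Stranded reagents from fragments of 100 to 500 nt and read as 50 nt single reads, and small RNA libraries were made with NEBNext reagents, per the labels' protocols.

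The deposited long RNA table held raw counts for 20921 gene symbols, 22 of which had been turned into dates and are not named here. STAR, Salmon and DESeq2 are named in the submitters' processing notes with builds mm10 and GRCm38, FastQC and MultiQC with them, and their versions are not given in the sources used here. The deposited transcript table held estimated counts, rounded to whole numbers, for 54755 transcripts, and was used for shares of transcript types only. The deposited normalised signal table held 49588 features, equal within 0.01 reads to the raw counts times 1 factor per library for at least 99.9952% of the symbols in both, and was used as an alternative after its factors were divided out. The deposited small RNA tables held raw counts for 1567 clusters of reads, of which 197 are miRNAs, 102 are tRNAs and 2 are Y RNAs in tables of their own. How clusters were made is not given in the sources used here. Symbols matched the reference gene names in 97.5% of cases, and 602 clusters had no annotation and named no gene.

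Depth was 8340645 to 51003994 counts per long RNA library, and 567301 to 12231533 after 92 rRNA and 31 control features were removed. RNP libraries were the shallowest. Small RNA libraries held 2099356 to 10449034 counts. Wilson intervals (95%) of shares and exact Poisson intervals of counts cover counting error only.

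The comparisons, lists and alternatives were chosen before the data were examined, except where noted as chosen after. Each fraction was compared with cells, exosomes with small microvesicles, RNPs with exosomes, and the PDGFR line with the EGFR line, for long RNA genes, miRNAs and tRNAs. The model in edgeR 4.0.16 was line plus fraction over 8 libraries, with 3 residual degrees of freedom, TMM factors, a low-count filter by fraction, quasi-likelihood tests and adjusted p by the Benjamini-Hochberg method with a threshold of 0.05. As each combination was measured once, the spread is how far the lines differ in their fraction changes. The log2 fold change of a fraction is thus a mean over lines. That of the lines is a mean over fractions, which are not independent replicates of a line. miRNA and tRNA tests were scaled within their own table, so their changes are relative to other miRNAs or tRNAs. SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F. It thus restates the test and is not a separate estimate of error. Lists of genes (31) and of miRNAs (10) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. Lists with no measured member were not tested.

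Genes were named by a rule fixed before the data were examined. It takes the targeted genes, then the 6 highest and 6 lowest log2 fold changes past the threshold with the same sign in both lines (in all 4 fractions for the lines) and a mean of at least 10 CPM. Predicted genes and pseudogenes are left out, and where none passes, the 3 highest and 3 lowest are given as not past the threshold. From each list it takes up to 4 members past the threshold, or else the 2 most abundant, and from each fraction the 5 most abundant. For miRNAs it takes 5 and 5, and for tRNAs 3 and 3. Where a group had 0 counts, the fold is a bound from a floor of 3 counts over the group. With 1 to 3 counts it is a ratio of library-scaled counts with an exact conditional interval.

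Alternatives were RLE size factors, library totals alone, DESeq2 1.42.0, no low-count filter, a mean of at least 10 CPM, rRNA kept, line or fraction left out of the model, extracellular fractions only for the lines, small RNA library sizes from all clusters, and each library left out in turn. Added after the data were seen were removal of 5 rRNA-like loci, the reads recovered from the normalised table, and both RNP libraries left out together. DESeq2 was run on all genes with its own filter. Library sizes from all small RNA clusters were used without TMM factors, so the total and the scaling changed together. The fit was tested on simulated data with 200 changed genes per comparison among 11564, drawn with the fitted spread. It recovered 10.6% of 64-fold changes for RNPs against cells, 27.3% for exosomes against cells, 34.8% for exosomes against small microvesicles, 22.7% for RNPs against exosomes and 57.6% between lines. Similarity used Spearman's rho on log2(CPM + 1). R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The normalised tables of transcripts and small RNAs were not used here. No reads were realigned.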

Results

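Long RNA and small RNA libraries were collected from mouse glioma cells and from 3 fractions of their conditioned medium. The EGFR line overexpressed human EGFR and was labelled Ink4a/Arf-null and PTEN-null. The PDGFR line overexpressed human PDGFRA and was labelled p53-null. Small microvesicles were held on a 0.22 µm filter and exosomes on a 0.02 µm filter. Ribonucleoproteins (RNPs) were concentrated on a 3 kDa column from the medium left after both filters. Fraction names follow the labels. Each line, fraction and kind of RNA had 1 library, so 16 libraries were compared. Long RNA counts summed to 51003994, 10649295, 15428470 and 8349298 for the EGFR line (cells, small microvesicles, exosomes and RNPs) and to 50014518, 20811505, 24026603 and 8340645 for the PDGFR line. Without rRNA and control RNAs, these sums were 12231533, 2643614, 1922451 and 567572, and 11119864, 2353181, 698657 and 567301. Small RNA clusters held 5365595, 2099356, 8100524 and 4116697 counts (EGFR) and 6606007, 2776171, 10449034 and 7262365 counts (PDGFR). Fractions were compared with cells and with each other, and the lines with each other, for genes, miRNAs and tRNAs. Y RNAs, RNA classes and the similarity of libraries were described without a test.

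The class of small RNA that filled a library depended on the fraction. miRNAs held 83.5% and 87.1% of counts in cells (EGFR line, then PDGFR line, here and below) and 88.8% and 93.4% in exosomes. In small microvesicles they held 41.2% and 52.8% and in RNPs 25.2% and 31.7%. tRNAs held 36.3% and 51.4% in RNPs, against 2.55% and 3.26% in cells, 3.66% and 5.93% in small microvesicles and 0.243% and 0.99% in exosomes. Clusters that matched repeats only held 30.6% and 18.9% in small microvesicles and 27.7% and 12.6% in RNPs, against 5.52% and 4.64% in cells and 6.85% and 2.73% in exosomes. Other non-coding RNA genes, a class with snoRNAs and snRNAs, held 5.75% and 3.22% in cells and 1.85% and 0.736% in RNPs. These shares were not tested, and with 1 library per bar their intervals cover counting error only.

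**Figure D1:**
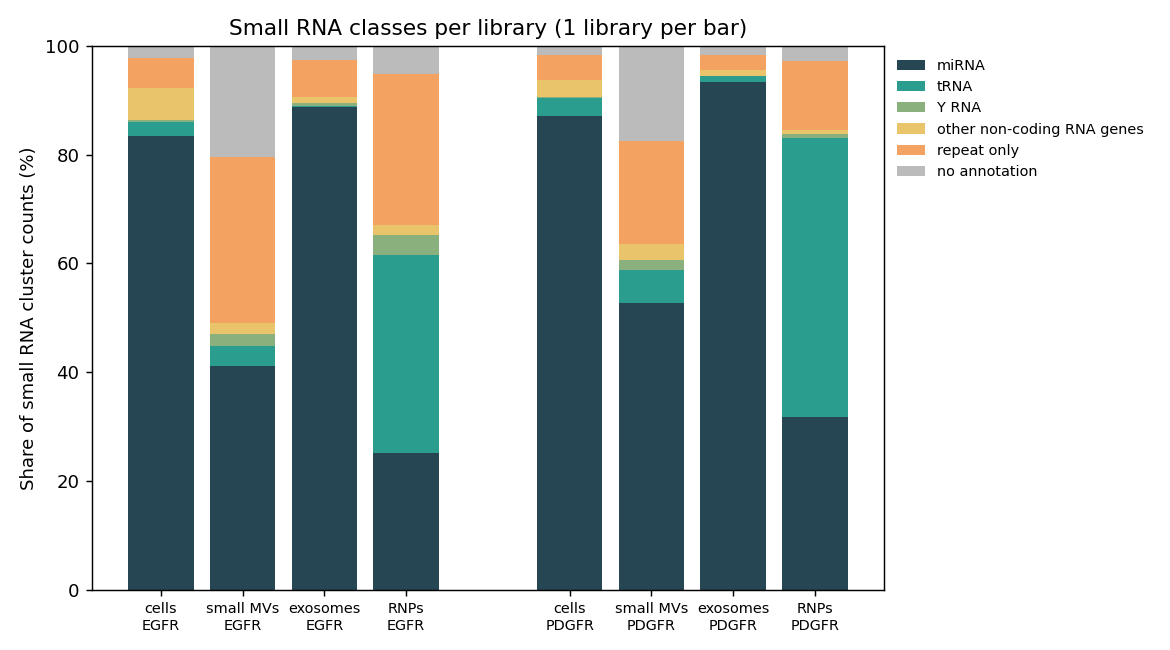
Share of all small RNA cluster counts (%) held by 6 classes, with 1 bar per library grouped by line and fraction. The tRNA share was 51.4% in PDGFR RNPs and 0.99% in PDGFR exosomes.

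Long RNA classes also parted the fractions. Mitochondrial mRNAs held 1.14% and 1.91% of long RNA counts in cells, 0.0547% and 0.505% in small microvesicles and 0.00395% and 0.0381% in exosomes. In RNPs they held 0.891% and 0.0673%, lower than in cells in both lines. Small structural RNAs, a list with 7SL, 7SK, RNase P, vault and spliceosomal RNAs, held 31.2% and 41.2% in RNPs against 2.96% and 3.26% in cells, or 10.5 and 12.6 times cells, and 3.29 and 4.18 times with rRNA kept in the total. Ribosomal protein mRNAs held 2.23% and 2.86% in small microvesicles, 1.33% and 1.5% in cells and 0.642% and 0.394% in RNPs. With rRNA kept in the total, small microvesicles held 0.559% and 0.326% and cells 0.319% and 0.334%, so the difference stayed in the EGFR line and was lost in the PDGFR line. Histone mRNAs held 0.386% and 0.199% in cells and 0.0955% and 0.0749% in RNPs. Olfactory receptor genes held 0.36% and 1.66% in RNPs and 0.0198% and 0.0418% in cells, or 18.2 and 39.6 times cells, and 5.67 and 13.1 times with rRNA kept. Before their removal, rRNA genes held 76% and 77.7% of all counts in cells, 74.2% and 87.8% in small microvesicles, 87.2% and 96.8% in exosomes and 84% and 85.6% in RNPs. The rRNA-like loci Lars2, Mir6236, Gm15564, Gm15662 and Gm26917 were left in and held 21.6% and 24.8% in cells and 22.42% and 47.8% in small microvesicles.

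The most abundant genes differed between fractions as well. Lars2 ranked among the 5 highest genes of every fraction, with counts of 1581253, 332645, 160288 and 86488 in the EGFR line and 1252862, 599919, 173816 and 50583 in the PDGFR line. Lars2, Mir6236, AA474408, Gm15662 and Gm26917 led in cells, and Mir6236 and Gm15662 also stood among the 5 highest in small microvesicles. The 7SL copies Rn7s1 and Rn7s2 share most of their sequence, so their near-equal counts cannot be told apart with certainty. They joined the 5 highest in small microvesicles and RNPs, and Rn7s2 also in exosomes. Rpph1, the RNA of RNase P, joined them in exosomes and RNPs, with 44141, 22753, 9921 and 4154 counts in the EGFR line and 67018, 29029, 49933 and 72329 in the PDGFR line. RP24-286J21.7 stood among the 5 highest in exosomes, with 13568, 117651, 106277 and 1827 counts (EGFR) and 961, 1952, 9538 and 190 (PDGFR). The 5 highest genes of each library took 27.6% and 26.1% of its counts in cells and 55.3% and 50.4% in RNPs. By the transcript table, protein-coding transcripts held 45.7% and 45.8% in cells, 63.6% and 20.8% in exosomes, and 11.9% and 9.87% in RNPs. These are shares of the estimated transcript counts without rRNA and control RNAs. In RNPs they stand for 153155 and 115928 counts, of a total larger than the gene totals of 567572 and 567301. The low RNP shares thus depend on the total used, and cannot be set beside the gene shares above.

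**Figure D2:**
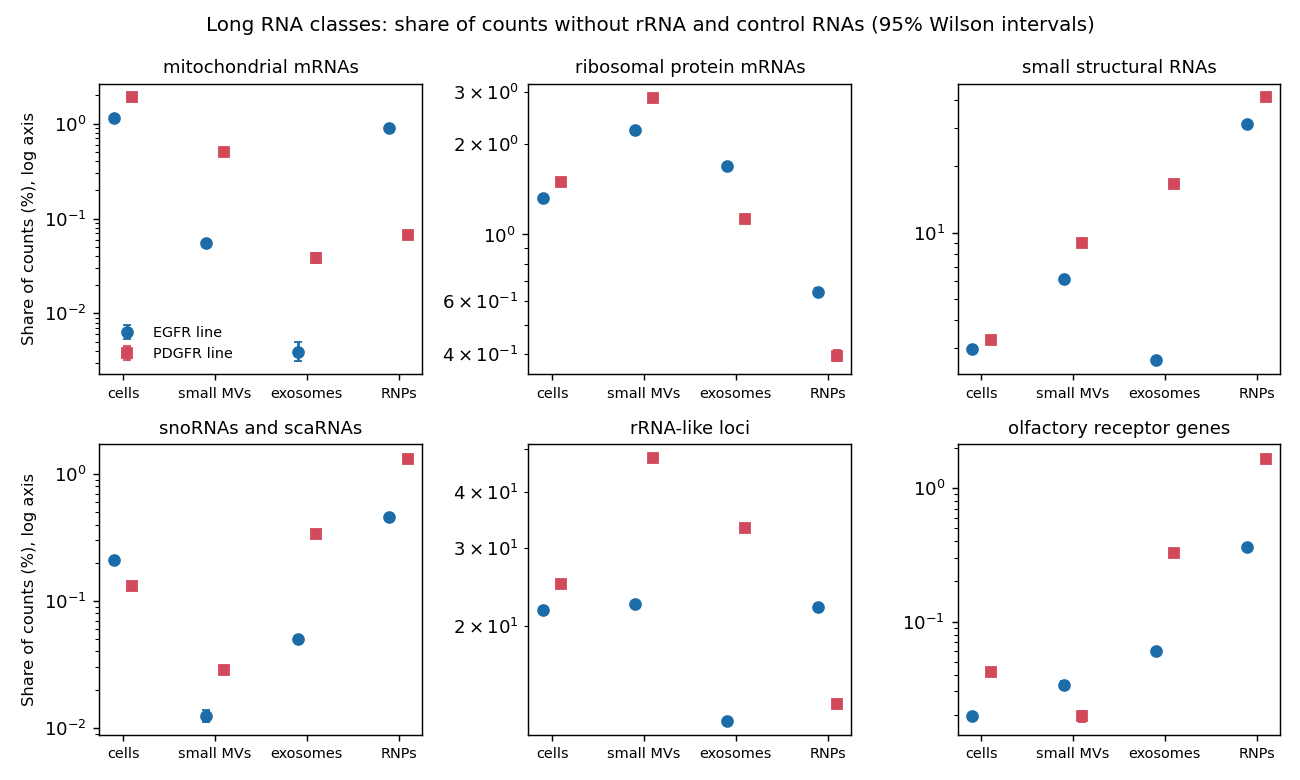
Share of long RNA counts without rRNA and control RNAs (%, log axis) per fraction for 6 classes, with circles for the EGFR line, squares for the PDGFR line and bars for 95% Wilson intervals. Small structural RNAs reached 31.2% and 41.2% in RNPs.

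Cells of the 2 lines resembled each other most for long RNA, with Spearman's rho 0.862 across genes, which are not independent replicates. EGFR small microvesicles and EGFR exosomes were each other's nearest library, with rho 0.81. RNPs of both lines lay nearest PDGFR exosomes, with rho 0.583 and 0.577. These were the shallowest long RNA libraries without rRNA and control RNAs (567572, 567301 and 698657 counts), so resemblance cannot be told from depth. For miRNAs, the nearest library came from the same line in 8 of 8 cases. EGFR small microvesicles and exosomes had rho 0.947, PDGFR exosomes and RNPs had 0.956, and cells had 0.869 and 0.883 with the exosomes of their own line. With a mean of at least 10 CPM, the long RNA values were lower: 0.762 for cells and 0.711 for EGFR small microvesicles and exosomes. The RNPs of the 2 lines were then nearest each other, at 0.431, and for miRNAs EGFR cells were nearest PDGFR cells, at 0.856.

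**Figure D3:**
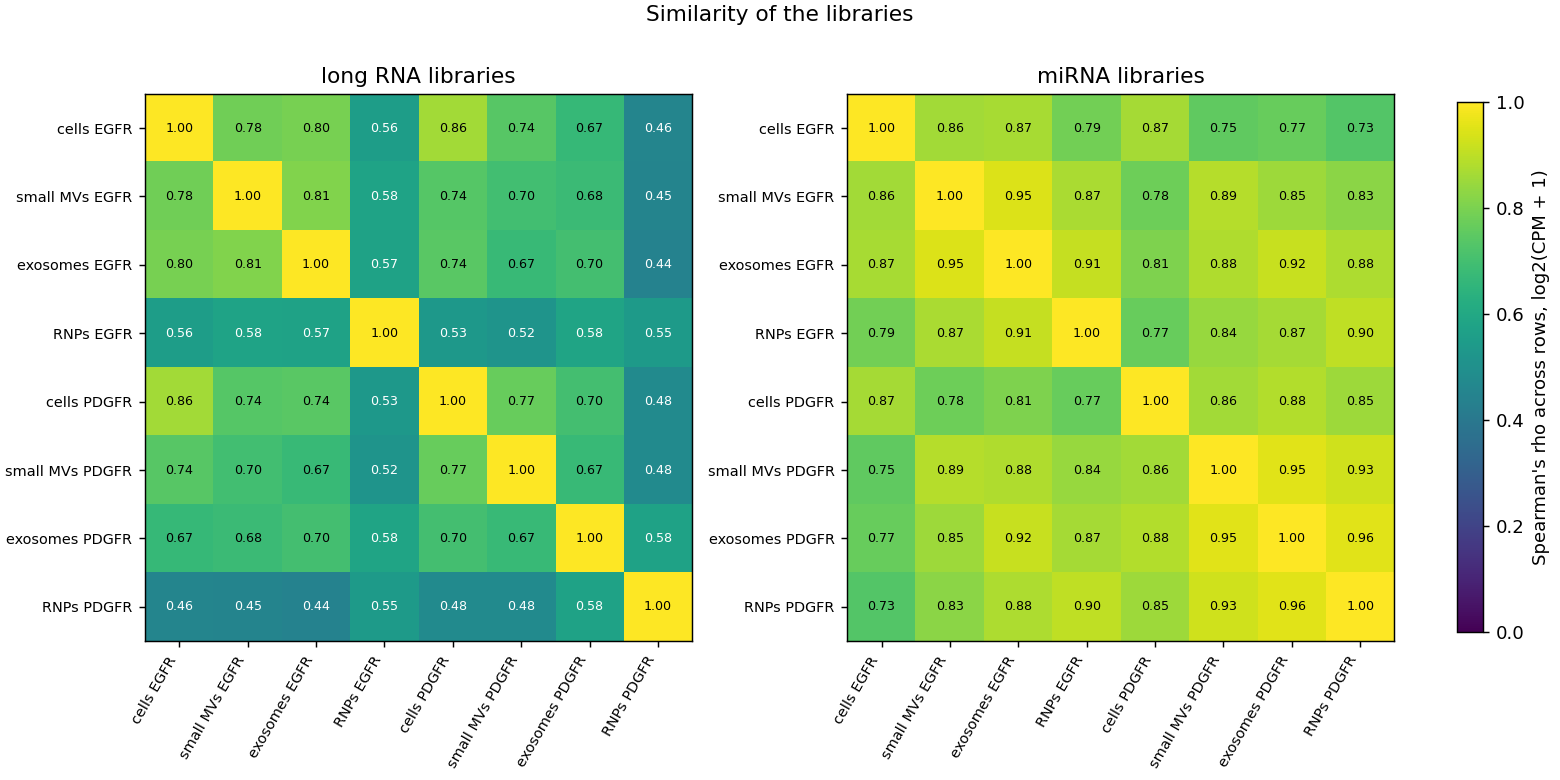
Spearman's rho between every pair of libraries on log2(CPM + 1), for long RNA genes (left) and miRNAs (right), with 1 cell per pair on a colour scale from 0 to 1. Long RNA of the cells gave 0.862 between lines, and miRNAs of PDGFR exosomes and RNPs gave 0.956.

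Small microvesicles held relatively more ribosomal protein mRNA and less mitochondrial, snoRNA and immediate early RNA than cells, as sets of genes scaled without rRNA and at the preset correlation only. With an estimated correlation these 4 lists had adjusted p = 0.365, 0.765, 0.765 and 0.365, in that order. No single member of these sets passed the threshold over all genes. Of 78 ribosomal protein mRNAs, 74 had a positive fold change (median log2 fold change 1.57, adjusted p = 5.1e-23, and adjusted p = 0.365 with an estimated correlation). Rpsa (2.37, SE 1.26, adjusted p = 0.554) and Rplp0 (2.37, SE 1.17, adjusted p = 0.519) were the most abundant. Translation factors (median log2 fold change 0.55, adjusted p = 0.00225, and adjusted p = 0.765 with an estimated correlation), nuclear OXPHOS mRNAs (0.60, adjusted p = 0.00598 and 0.765) and snoRNA host lncRNAs (1.20, adjusted p = 0.00225 and 0.365) went the same way, here and below with the preset p first and the p of an estimated correlation second.

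Other sets lay on the lower side in small microvesicles, where the median over all genes was -0.44. Of 13 mitochondrial mRNAs, 0 had a positive fold change, and 3 fell adjusted over the list alone (median log2 fold change -2.28, adjusted p = 0.000405, and adjusted p = 0.765 with an estimated correlation). For mt-Co1 the log2 fold change was -2.04, SE 1.60, adjusted p = 0.764. Of 45 snoRNAs and scaRNAs, 6 fell adjusted over the list alone (median log2 fold change -2.70 (-2.69 with members at 0 set to their bound), adjusted p = 6.89e-06, and adjusted p = 0.765 with an estimated correlation), with Rnu3a at -2.68 and Rnu3b1 at -4.0, neither past the threshold. Of 16 immediate early genes, 5 fell adjusted over the list alone (median log2 fold change -2.65, adjusted p = 1.93e-06, and adjusted p = 0.365 with an estimated correlation), with Egr1 at -3.66 and Jun at -2.46, not past the threshold over all genes. Extracellular matrix (-1.75, adjusted p = 6.89e-06 and 0.436), interferon response (-2.85 or -2.55 at the bound, adjusted p = 2.88e-05 and 0.365) and cholesterol synthesis genes (-1.67, adjusted p = 0.00225 and 0.765) lay lower. So did fibroblast and pericyte markers (-2.04 or -1.61 at the bound, adjusted p = 0.022 and 0.765), nuclear lncRNAs (-1.73, adjusted p = 0.0446 and 0.765) and ER chaperones (-1.71, adjusted p = 0.0491 and 0.802). Small structural RNAs passed in the upward direction at the preset correlation, with a median near 0 (-0.02, adjusted p = 0.0323 and 0.931) and 8 of 17 members positive.

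Gene by gene, edgeR called 1 of 11564 genes higher and 0 lower in small microvesicles than in cells. The 1 call was the predicted gene Gm20400, and 1134 genes had an unadjusted p under 0.05. The largest rises outside predicted genes, none past the threshold, were Mettl5os (8.09, SE 1.74, adjusted p = 0.122), Olfr1039 (6.99, SE 1.99, adjusted p = 0.25) and Myo1h (6.77, SE 1.76, adjusted p = 0.201). The largest falls, also not past the threshold, were D1Ertd622e (at least 104-fold lower, adjusted p = 0.122), Fgd4 (at least 33-fold lower, adjusted p = 0.176) and Sgms2 (at least 62.2-fold lower, adjusted p = 0.122). DESeq2 called 236 (126 higher, 110 lower), and edgeR without the low-count filter called 63 (20 higher, 43 lower). Leaving out each library in turn gave 11 (without PDGFR cells) to 147 (without PDGFR RNPs), over 1.5 times off for 8 of 8. The edgeR self-test recovered 42.4% of 64-fold changes and 8.96% of 16-fold changes in this comparison.

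Exosomes held almost no mitochondrial mRNA and relatively more of a few RNAs that cells barely held. Of 13 mitochondrial mRNAs, 13 fell adjusted over the list alone, although none passed over all genes (median log2 fold change -5.83 (-5.76 with members at 0 set to their bound), adjusted p = 5.76e-09, and adjusted p = 0.413 with an estimated correlation). mt-Co1 counts went from 33663 to 20 in the EGFR line and from 59998 to 68 in the PDGFR line, before scaling for depth (log2 fold change -5.82, SE 1.83, adjusted p = 0.19). For mt-Nd5 it was -5.56, SE 1.59, adjusted p = 0.144. Olfr965 was at least 183-fold higher than in cells and Olfr1130 at least 100-fold higher. Mettl5os (9.0, SE 1.74, adjusted p = 0.0272), Olfr1033 (8.63, SE 1.58, adjusted p = 0.0272), RP24-236E2.3 (7.67, SE 1.61, adjusted p = 0.0427) and RP24-236E2.2 (7.43, SE 1.39, adjusted p = 0.0272) also rose.

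Most lists past the set test at the preset correlation lay lower in exosomes than in cells. Of 24 extracellular matrix genes, 11 fell adjusted over the list alone (median log2 fold change -2.88, adjusted p = 1.76e-09, and adjusted p = 0.354 with an estimated correlation), with Col3a1 at -3.27 and Fn1 at -2.26, neither past the threshold over all genes. ER chaperones had 7 of 15 members that fell adjusted over the list alone (median log2 fold change -2.94 (-2.91 with members at 0 set to their bound), adjusted p = 0.00334, and adjusted p = 0.462 with an estimated correlation). Actin cytoskeleton (-1.98, adjusted p = 1.68e-05 and 0.413), interferon response (-3.52 or -3.44 at the bound, adjusted p = 1.68e-05 and 0.354), immediate early (-1.79, adjusted p = 0.000364 and 0.413) and vesicle biogenesis genes (-1.43, adjusted p = 0.000751 and 0.413) lay lower. In the vesicle list, Hsp90aa1 was at -2.11 and Hspa8 at -1.42, not past the threshold. Glycolysis (-1.73, adjusted p = 0.00108 and 0.453), cholesterol (-1.63, adjusted p = 0.00128 and 0.413), histone (-1.49, adjusted p = 0.00254 and 0.47), DNA replication (-1.75, adjusted p = 0.00276 and 0.413), mitosis (-1.49, adjusted p = 0.00517 and 0.413) and OXPHOS lists (-1.37, adjusted p = 0.00391 and 0.508) did too. So did mesenchymal glioma genes (-1.64, adjusted p = 0.00298 and 0.449) and fibroblast markers (-2.06, adjusted p = 0.00343 and 0.413). Ribosomal proteins (0.62, adjusted p = 0.000751 and 0.51) and small structural RNAs (1.99, adjusted p = 0.0111 and 0.663) were the 2 lists on the higher side. Their shares were 1.27 and 0.749, and 0.891 and 5.07 times cells (EGFR line, then PDGFR line). With rRNA kept, both classes lay below cells in both lines. edgeR called 22 of 11564 genes higher and 0 lower, with 1407 at an unadjusted p under 0.05, and DESeq2 called 689 (525 higher, 164 lower). The count was over 1.5 times off for 7 of 8 left-out libraries, from 9 (without PDGFR exosomes) to 334 (without PDGFR RNPs). With both RNP libraries left out the count was 0, with the rRNA-like loci removed 1, and with a minimum of 10 CPM 0.

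Between the vesicle fractions, snoRNAs and scaRNAs lay higher in exosomes than in small microvesicles, and mitochondrial and ribosomal protein mRNAs lay lower, as lists at the preset correlation only. Of 45 snoRNAs and scaRNAs, 4 rose adjusted over the list alone (median log2 fold change 3.19 (2.59 with members at 0 set to their bound), adjusted p = 7.38e-07, and adjusted p = 0.596 with an estimated correlation), with Rnu3a at 2.99 and Rnu3b1 at 2.38, neither past the threshold over all genes. Of 13 mitochondrial mRNAs, 8 fell adjusted over the list alone (median log2 fold change -3.48 (-3.71 with members at 0 set to their bound), adjusted p = 9.38e-05, and adjusted p = 0.596 with an estimated correlation), with mt-Co1 at -3.78. Ribosomal proteins (-0.99, adjusted p = 3.71e-08 and 0.596), translation factors (-1.10, adjusted p = 0.000467 and 0.596), OXPHOS (-1.81, adjusted p = 4.51e-07 and 0.596), actin (-1.61 or -1.43 at the bound, adjusted p = 8.79e-07 and 0.596), histone (-1.13 or -1.08 at the bound, adjusted p = 0.000575 and 0.596) and DNA replication genes (-0.93, adjusted p = 0.00143 and 0.596) lay lower. Mitosis (-1.05, adjusted p = 0.00143 and 0.596), vesicle (-1.0, adjusted p = 0.00212 and 0.596), matrix (-0.84, adjusted p = 0.00287 and 0.596) and glycolysis genes (-1.38, adjusted p = 0.0125 and 0.596) did as well. The most extreme genes, not past the threshold, were Olfr678 (at least 177-fold higher, adjusted p = 0.188), Vdr (at least 57.7-fold higher, adjusted p = 0.178) and Pou1f1 (at least 68.2-fold higher, adjusted p = 0.178) on the higher side. Myadm (at least 34.1-fold lower, adjusted p = 0.31), Amn1 (262-fold lower, counting interval 72.4 to 2168, adjusted p = 0.178) and Tmem151a (at least 11.7-fold lower, adjusted p = 0.338) stood on the lower side. edgeR called 0 of 11564 genes, with 1091 at an unadjusted p under 0.05, and DESeq2 called 154 (110 higher, 44 lower). With 1 library left out, the count ran from 2 (without PDGFR exosomes) to 110 (without PDGFR RNPs), over 1.5 times off for 8 of 8 libraries.

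RNPs differed from cells more than either vesicle fraction did by this test. Genes that cells barely held led the rises. Pou1f1, which encodes a pituitary transcription factor, had counts of 1, 0, 3 and 252 in the EGFR line and 11, 0, 121 and 1246 in the PDGFR line (log2 fold change 13.63, SE 2.06, adjusted p = 0.00086). The olfactory receptor genes Olfr1039 (13.62, SE 2.46, adjusted p = 0.00168), Olfr60 (13.00, SE 1.98, adjusted p = 0.00086), Olfr1130 (at least 2611-fold higher, adjusted p = 0.00086) and Olfr965 (at least 1709-fold higher, adjusted p = 0.00106) rose, and so did Ceacam3 (11.94, SE 1.79, adjusted p = 0.00086). The 6 largest falls had 0 counts in both RNP libraries. The termination factor gene Etf1 had 15883 and 6883 counts in cells (at least 107-fold lower, adjusted p = 0.00515). Pnrc2 (at least 51.8-fold lower, adjusted p = 0.00704), Gpsm2 (at least 30.2-fold lower, adjusted p = 0.009), Tmed2 (at least 27.3-fold lower, adjusted p = 0.00573), Casp8ap2 (at least 12.9-fold lower, adjusted p = 0.0181) and Uqcc1 (at least 8.94-fold lower, adjusted p = 0.04) fell.

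Single small non-coding RNAs rose in RNPs, and 2 lists of them passed at the preset correlation only. Of 45 snoRNAs and scaRNAs, 5 rose over all genes and 15 adjusted over the list alone, and none fell (median log2 fold change 1.65 (2.41 with members at 0 set to their bound), adjusted p = 2.96e-06, and adjusted p = 0.74 with an estimated correlation). Scarna3b (1780-fold higher, counting interval 291 to 73101, adjusted p = 0.00851), Snora78 (7.68, SE 1.73, adjusted p = 0.00782), Scarna3a (6.74, SE 1.68, adjusted p = 0.0161) and Scarna13 (4.71, SE 1.36, adjusted p = 0.0427) were among them. The share of snoRNAs and scaRNAs in RNPs was 2.2 and 10.1 times cells (EGFR line, then PDGFR line). With rRNA kept it was 0.685 and 3.34 times, so the direction turned in the EGFR line. Of 17 small structural RNAs, 2 rose and 1 fell over all genes, with 6 and 2 adjusted over the list alone (median log2 fold change 2.74, adjusted p = 0.000151, and adjusted p = 0.74 with an estimated correlation). The vault RNA Vaultrc5 rose (7.93, SE 1.74, adjusted p = 0.00663), the 7SL copy Rn7s6 rose (5.49, SE 1.22, adjusted p = 0.00683) and the U2 snRNA copy Rnu2-10 fell (-5.69, SE 1.57, adjusted p = 0.0318). Copies of 7SL and U2 are near-identical, so the split of reads among them is uncertain.

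A few genes of cell division and protein folding fell in RNPs, and both lists passed at the preset correlation only. Of 22 mitosis and cell cycle genes, 2 fell, Cdk1 (at least 10.3-fold lower, adjusted p = 0.0341) and Nusap1 (52.2-fold lower, counting interval 9.36 to 2061, adjusted p = 0.0287), and the list passed (median log2 fold change -2.44 (-2.25 with members at 0 set to their bound), adjusted p = 0.00308, and adjusted p = 0.74 with an estimated correlation). Of 15 ER chaperones and stress genes, Pdia6 fell (32.2-fold lower, counting interval 8.91 to 266, adjusted p = 0.0443) and 7 fell adjusted over the list alone (median log2 fold change -2.93 (-2.06 with members at 0 set to their bound), adjusted p = 0.0148, and adjusted p = 0.74 with an estimated correlation). Cholesterol synthesis (-1.95 or -1.84 at the bound, adjusted p = 0.0304 and 0.74) and OXPHOS genes (-1.83 or -1.26 at the bound, adjusted p = 0.0468 and 0.822) lay lower with no single call. Among vesicle genes Smpd3 rose (6.65, SE 1.47, adjusted p = 0.00686) and Anxa5 fell (-4.38, SE 1.29, adjusted p = 0.0466). Among histones Hist1h4m rose (6.54, SE 1.45, adjusted p = 0.00678) and Hist1h2bl fell (at least 11.8-fold lower, adjusted p = 0.0282). Among ribosomal proteins Rpl27 rose (5.60, SE 1.60, adjusted p = 0.0392) and Rpl36 fell (at least 12.5-fold lower, adjusted p = 0.0152), and both have processed copies that can share reads. mt-Co1 (1.54, SE 1.57, adjusted p = 0.589) did not pass. On the TMM scale 8 of 13 mitochondrial mRNAs had a positive fold change, but their share in RNPs was 0.784 and 0.0352 times that of cells (EGFR line, then PDGFR line), and 0.245 and 0.0116 times with rRNA kept.

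Single markers of neural, immune and vessel cells rose in RNPs from low counts. Cx3cr1 rose (1353-fold higher, counting interval 440 to 6755, adjusted p = 0.00161), and the microglia list passed with only 3 members measured, of which 1 rose (median log2 fold change 7.61, adjusted p = 0.0148, and adjusted p = 0.74 with an estimated correlation). Slc1a3 (6.88, SE 1.88, adjusted p = 0.0302), Plp1 (4.46, SE 1.22, adjusted p = 0.0302) and Dcx (7.10, SE 2.05, adjusted p = 0.0442) rose. Their lists did not pass: astrocyte (-1.58 or -0.68 at the bound, adjusted p = 0.937 and 0.966), oligodendrocyte (1.16, adjusted p = 0.0894 and 0.74), neuron (0.51 or 0.97 at the bound, adjusted p = 0.167 and 0.74) and proneural (0.68, adjusted p = 0.138 and 0.74). Among 3 endothelial markers (-3.26 or -1.37 at the bound, adjusted p = 0.983 and 0.987, not past), Pecam1 rose (9.13, SE 2.04, adjusted p = 0.0071) from counts in the PDGFR line alone, and its log2 fold change was -2.05 (adjusted p = 0.959) without the PDGFR RNPs. edgeR called 589 of 11564 genes, 511 higher and 78 lower, with 2130 at an unadjusted p under 0.05, and DESeq2 called 1270 (1063 higher, 207 lower). With library totals alone as the scale the count was 2212 (391 higher, 1821 lower), since the median log2 fold change moved by -1.82. The direction of the whole set thus followed the scale, and TMM values are relative to the bulk of genes. With a minimum of 10 CPM the count was 248 (234 higher, 14 lower). Leaving out each library in turn gave 209 (without PDGFR cells) to 1056 (without EGFR small microvesicles), over 1.5 times off for 3 of 8.

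RNPs held relatively more mitochondrial and matrix mRNA than exosomes, as lists at the preset correlation only, for mitochondrial mRNAs mainly in the EGFR line. All 13 mitochondrial mRNAs had a positive fold change and 12 rose adjusted over the list alone (median log2 fold change 6.30 (6.01 with members at 0 set to their bound), adjusted p = 2.36e-07, and adjusted p = 0.69 with an estimated correlation). Their share went from 0.00395% in exosomes to 0.891% in RNPs in the EGFR line, and only from 0.0381% to 0.0673% in the PDGFR line. mt-Co1 was at 7.36 (adjusted p = 0.108) and mt-Nd5 at 6.07 (adjusted p = 0.103). Of 24 matrix genes, 22 had a positive fold change and 7 rose adjusted over the list alone (median log2 fold change 1.68, adjusted p = 1.29e-07, and adjusted p = 0.69 with an estimated correlation), with Col3a1 at 4.71, not past over all genes. snoRNAs (1.5 or 1.82 at the bound, adjusted p = 4.06e-05 and 0.69), fibroblast markers (1.75, adjusted p = 0.00703 and 0.69), actin (0.43, adjusted p = 0.012 and 0.69), small structural RNAs (0.59 or 0.78 at the bound, adjusted p = 0.0364 and 0.793) and microglia markers (2.65, adjusted p = 0.0364 and 0.69) also lay higher. Olfr1321 (at least 163-fold higher), mt-Ts1 (at least 125-fold higher) and Pappa2 (at least 63.5-fold higher) had the largest positive values. RP23-212C9.3 (at least 57.4-fold lower), Etf1 (at least 30.7-fold lower) and Fgd6 (at least 39.3-fold lower) had the largest negative values, and all 6 had adjusted p = 0.0941, not past the threshold. edgeR called 0 of 11564 genes, with 1917 at an unadjusted p under 0.05, and DESeq2 called 905 (574 higher, 331 lower). The count was over 1.5 times off for 8 of 8 left-out libraries, from 13 (without EGFR exosomes) to 448 (without PDGFR small microvesicles).

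Trp53 was lower in the p53-null line and Cdkn2a in the Ink4a/Arf-null line. Trp53 had 607, 153, 13 and 1 counts in the EGFR line and 13, 0, 0 and 0 in the p53-null PDGFR line (-6.47, SE 1.58, adjusted p = 0.045). Cdkn2a, the Ink4a/Arf gene, had 30, 14, 2 and 0 counts in the EGFR line and 1102, 134, 14 and 10 in the PDGFR line (4.92, SE 1.01, adjusted p = 0.0146). Pten had 786, 141, 137 and 46 counts in the PTEN-null EGFR line and 793, 99, 26 and 20 in the PDGFR line. Whole-gene counts include the parts outside a deletion, so they check nothing for a partial deletion. Both receptors were human by the labels, so counts of the mouse genes need not show them. Mouse Pdgfra had 175, 68, 18 and 3 counts (EGFR line) and 5024, 80, 52 and 1 (PDGFR line), and mouse Egfr 281, 0, 1 and 22 and 1328, 10, 1 and 0.

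Apart from these, the PDGFR line was higher in genes that the EGFR line did not show in any fraction. Eno1b (at least 817-fold higher, adjusted p = 0.00167), Irx1 (at least 721-fold higher, adjusted p = 0.00287), Cacna1g (at least 614-fold higher, adjusted p = 0.00334) and Kcnj2 (at least 65.8-fold higher, adjusted p = 0.0103) had 0 counts in all 4 EGFR libraries. Lrp2 (823-fold higher, counting interval 147 to 32540, adjusted p = 0.0071) and Sned1 (8.91, SE 1.34, adjusted p = 0.00167) also rose. Eno1b is nearly identical to Eno1, so its reads cannot be assigned to 1 of them with certainty. On the lower side, Klk10 (at least 155-fold lower, adjusted p = 0.0143) and Tril (at least 125-fold lower, adjusted p = 0.0113) had 0 counts in all 4 PDGFR libraries. B3galt5 (502-fold lower, counting interval 89.7 to 19851, adjusted p = 0.00167), Slc6a15 (437-fold lower, counting interval 121 to 3617, adjusted p = 0.00193), Rnf144a (508-fold lower, counting interval 90.9 to 20096, adjusted p = 0.00214) and Epb41l4b (-7.88, SE 1.21, adjusted p = 0.00167) also fell.

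**Figure D4:**
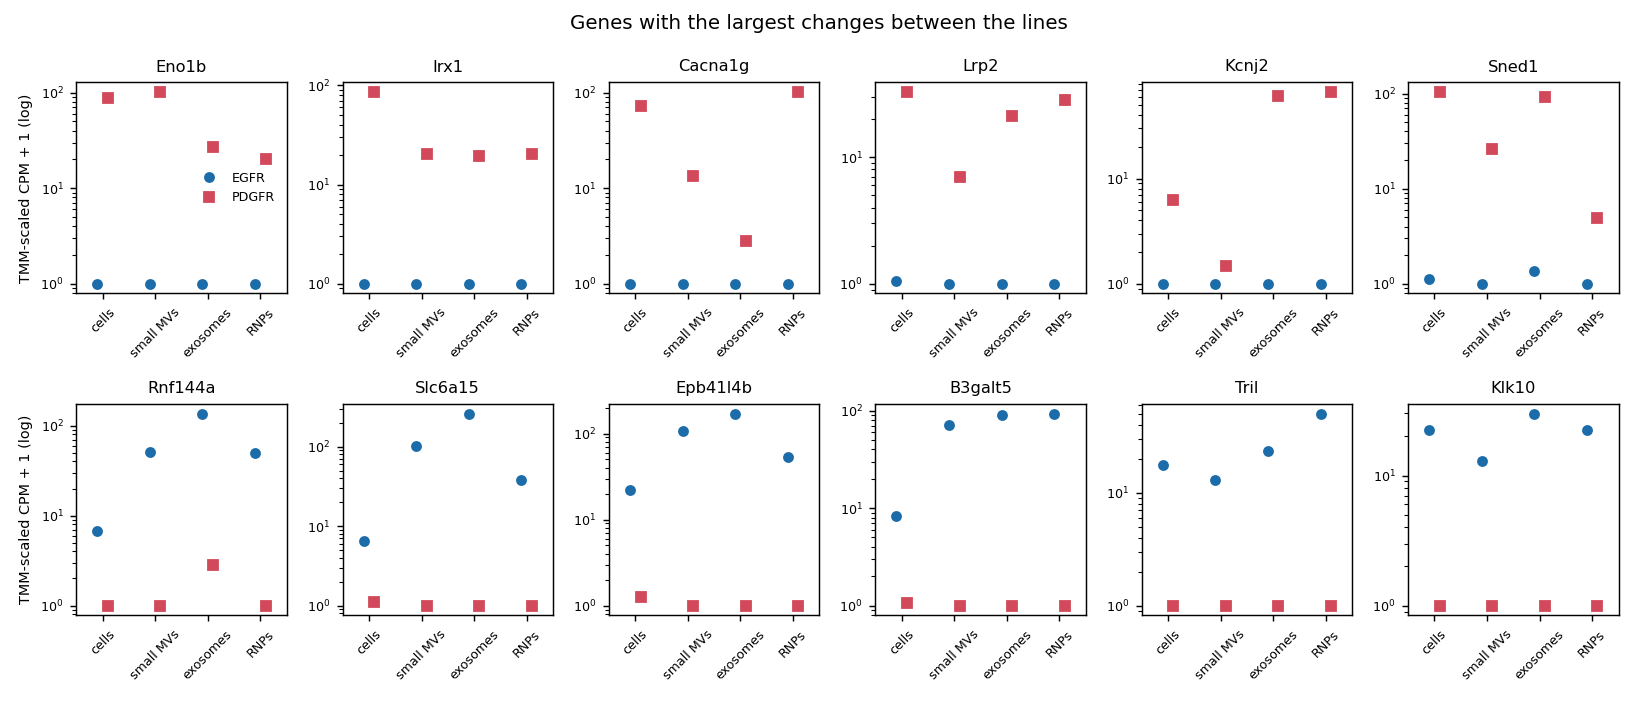
TMM-scaled CPM + 1 (log axis) of the 6 genes with the largest rise (top) and the 6 with the largest fall (bottom) in the PDGFR line against the EGFR line, with 1 point per library, circles for EGFR and squares for PDGFR. Irx1 had 0 counts in all EGFR libraries and 1621, 42, 10 and 5 counts in the PDGFR libraries.

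Single matrix, contractile and lineage genes also differed between the lines, while the matrix (-0.26, adjusted p = 0.216 and 0.764) and actin lists (0.39, adjusted p = 0.0765 and 0.751) did not pass. Bgn (5.48, SE 1.16, adjusted p = 0.0171) and Lox (4.42, SE 0.96, adjusted p = 0.0202) rose in the PDGFR line among 24 matrix genes, and Tpm2 rose among 23 actin cytoskeleton genes (4.57, SE 1.0, adjusted p = 0.0203). The endothelial gene Cdh5 (at least 252-fold higher, adjusted p = 0.0203) and the neuronal gene Stmn2 (5.21, SE 1.19, adjusted p = 0.0286) rose. The endothelial (median 2.34), neuron (-1.28) and proneural lists (0.35) did not pass. The proneural gene Erbb3 fell (-4.47, SE 1.03, adjusted p = 0.0317), and so did Rps2 among 78 ribosomal proteins (-7.71, SE 1.18, adjusted p = 0.00167), with 4286 and 95 counts in cells. Rps2 has many processed copies, so a different split of reads among them is an open alternative. As sets, immediate early genes (1.45, adjusted p = 0.00213 and 0.702), snoRNAs (1.09, adjusted p = 0.00109 and 0.751) and small structural RNAs (0.91, adjusted p = 0.00499 and 0.751) lay higher in the PDGFR line and DNA replication genes lower (-1.06, adjusted p = 0.0172 and 0.702), with no single member called. Trp53 itself was the only member of the list of 20 p53 targets to fall, and the list did not pass (-1.21, adjusted p = 0.143 and 0.702). edgeR called 128 of 11564 genes, 67 higher and 61 lower, with 1465 at an unadjusted p under 0.05, and DESeq2 called 683 (359 higher, 324 lower). The libraries of a line were its cells and fractions of its medium, so these calls describe agreement across fractions and not across replicates of a line. With library totals alone the count was 130 (45 higher, 85 lower), without the low-count filter 315 (164 higher, 151 lower), and without the RNP libraries 37 (14 higher, 23 lower). With 1 library left out, the count ran from 63 (without PDGFR exosomes) to 394 (without EGFR cells), over 1.5 times off for 8 of 8 libraries.

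Among miRNAs, miRNAs that cells barely held rose most in small microvesicles, and miR-122 and miR-143 rose with them. Mir6239 (at least 1209-fold higher, adjusted p = 0.00575), Mir5108 (8.58, SE 0.90, adjusted p = 0.00213), Mir5112 (7.95, SE 0.85, adjusted p = 0.00213), Mir10b (5.75, SE 1.67, adjusted p = 0.0372) and Mir6236 (4.60, SE 0.53, adjusted p = 0.00216) rose. Mir6236 is 1 of the 5 rRNA-like loci. Mir122 rose (4.01, SE 0.81, adjusted p = 0.0113), as did Mir143 (2.07, SE 0.32, adjusted p = 0.00575), Mir192 (1.77, SE 0.31, adjusted p = 0.00693) and Mir218-1/Mir218-2 (1.72, SE 0.39, adjusted p = 0.0173). Among glioma-associated miRNAs, Mir21a (1.23, SE 0.28, adjusted p = 0.0173), Mir7-2/Mir7-1 (0.94, SE 0.24, adjusted p = 0.0239) and Mir221 (0.90, SE 0.25, adjusted p = 0.0337) rose. Mir193b (50.8-fold lower, counting interval 17.3 to 247, adjusted p = 0.0234), Mir5117 (-5.30, SE 0.69, adjusted p = 0.00575), a second row of let-7d (-5.14, SE 0.44, adjusted p = 0.00131), Mir328 (-4.91, SE 0.56, adjusted p = 0.00216) and Mir365-1 (-3.74, SE 1.17, adjusted p = 0.0454) fell. The other let-7d row fell too (-1.38, SE 0.28, adjusted p = 0.0113), while let-7f-2 rose (0.97, SE 0.26, adjusted p = 0.0278). edgeR called 74 of 195 miRNAs, 40 higher and 34 lower. With library sizes from all small RNA counts and no TMM factors it called 81 (11 higher, 70 lower). miRNAs held a smaller share there, but which of these changes moved the calls was not tested. Under that scale Mir7-2/Mir7-1 was at -0.19, Mir221 at -0.18 and let-7f-2 at -0.14, so these 3 reversed. Leaving out each library in turn gave 22 (without PDGFR small microvesicles) to 84 (without EGFR RNPs), over 1.5 times off for 4 of 8.

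In exosomes, 5 of 12 let-7 members rose relative to other miRNAs and 4 of 8 members of the miR-17 clusters fell. Let-7g (1.90, SE 0.27, adjusted p = 0.00458), let-7c (1.72, SE 0.25, adjusted p = 0.00458) and let-7i (1.39, SE 0.24, adjusted p = 0.00578) rose, whereas the second row of let-7d fell (-6.10, SE 0.46, adjusted p = 0.0012). Mir92-2 (-2.27, SE 0.41, adjusted p = 0.0065), Mir18 (-2.18, SE 0.67, adjusted p = 0.0362), Mir17 (-2.12, SE 0.61, adjusted p = 0.0301) and Mir92-1 (-1.32, SE 0.42, adjusted p = 0.042) fell. Mir122 rose (6.22, SE 0.88, adjusted p = 0.00458), from 151 to 27673 counts in the EGFR line and from 1988 to 109418 in the PDGFR line before scaling. Mir6239 (at least 105-fold higher, adjusted p = 0.0111), Mir5108 (4.25), Mir5112 (3.82) and Mir6236 (3.28) rose again. Mir143 (2.07), Mir221 (1.42), Mir34c (1.40) and Mir218-1/Mir218-2 (1.30) rose. Neural miRNAs Mir128-1 (-2.78, SE 0.56, adjusted p = 0.00912), Mir9-2/Mir9-3 (-1.85, SE 0.35, adjusted p = 0.00737) and Mir29a (-0.82, SE 0.28, adjusted p = 0.046) fell. Mir5100 (at least 305-fold lower, adjusted p = 0.00538), Mir5117 (-10.53, SE 0.89, adjusted p = 0.00213), Mir328 (-6.59, SE 0.60, adjusted p = 0.00134) and Mir1249 (-4.60, SE 0.78, adjusted p = 0.00578) fell most. edgeR called 99 of 195 miRNAs, 44 higher and 55 lower. With library totals alone it called 75 (16 higher, 59 lower), and with library sizes from all small RNA counts 73 (15 higher, 58 lower). The count was over 1.5 times off for 4 of 8 left-out libraries, from 35 (without EGFR exosomes) to 101 (without EGFR RNPs).

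Few miRNAs passed the threshold between exosomes and small microvesicles, though 60 of 195 had an unadjusted p under 0.05, against 9.75 expected by chance. Mir155 (1.87, SE 0.42, adjusted p = 0.0492), let-7c (1.46, SE 0.25, adjusted p = 0.0251), Mir206 (1.44, SE 0.25, adjusted p = 0.0251) and let-7g (1.36, SE 0.26, adjusted p = 0.033) were the 4 that rose in exosomes. Mir5100 (at least 42.1-fold lower, adjusted p = 0.0471), Mir5119 (-5.39, SE 1.12, adjusted p = 0.0425), Mir5117 (-5.23, SE 0.85, adjusted p = 0.026), Mir5108 (-4.33, SE 0.68, adjusted p = 0.0251) and Mir5112 (-4.13, SE 0.70, adjusted p = 0.0251) fell. The neural miRNAs Mir128-1 (-2.64, SE 0.56, adjusted p = 0.0426) and Mir9-2/Mir9-3 (-1.96, SE 0.35, adjusted p = 0.0251) fell as well. edgeR called 14 of 195, 4 higher and 10 lower. DESeq2 called 43 (15 higher, 28 lower), library totals alone gave 16 (1 higher, 15 lower), and library sizes from all small RNA counts gave 17 (9 higher, 8 lower). With 1 library left out, the count ran from 0 (without EGFR small microvesicles) to 38 (without EGFR RNPs), over 1.5 times off for 6 of 8 libraries.

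In RNPs, miR-122 and let-7c rose, and 3 of 8 members of the miR-17 clusters and 3 of 6 neural miRNAs fell. Mir122 (7.98, SE 0.95, adjusted p = 0.00141) was at 11438 counts in the EGFR line and 61100 in the PDGFR line. Mir6239 (at least 1570-fold higher, adjusted p = 0.00219), Mir5108 (7.28, SE 0.88, adjusted p = 0.00141), Mir6236 (5.74, SE 0.56, adjusted p = 0.00139) and Mir5112 (5.73, SE 0.80, adjusted p = 0.00219) also rose. In the let-7 family, let-7c (2.28, SE 0.26, adjusted p = 0.00141), let-7g (1.82, SE 0.27, adjusted p = 0.00243) and let-7i (1.18, SE 0.24, adjusted p = 0.0085) rose and the second row of let-7d fell (-5.17, SE 0.44, adjusted p = 0.00132). Mir669c of the Sfmbt2 cluster rose (2.15, SE 0.45, adjusted p = 0.0103). Mir221 (1.55), Mir143 (1.49), Mir192 (1.18), Mir27b (1.10) and Mir7-2/Mir7-1 (0.92) rose.

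The miRNAs that fell in RNPs were led by Mir5117 (at least 359-fold lower, adjusted p = 0.00141), Mir671 (-6.94, SE 1.04, adjusted p = 0.0027), Mir328 (-6.04, SE 0.60, adjusted p = 0.00139), Mir92-2 (-5.29, SE 0.50, adjusted p = 0.00139) and Mir130b (-5.25, SE 0.68, adjusted p = 0.00187). Mir92-1 (-3.94, SE 0.47, adjusted p = 0.00141) and Mir17 (-2.54, SE 0.64, adjusted p = 0.0219) of the miR-17 clusters fell too. Mir128-1 (-3.41, SE 0.59, adjusted p = 0.00494), Mir9-2/Mir9-3 (-2.76, SE 0.36, adjusted p = 0.00187) and Mir338 (-2.58, SE 0.68, adjusted p = 0.0247) fell among neural miRNAs. edgeR called 86 of 195 miRNAs, 44 higher and 42 lower. These changes are relative to all miRNAs: with library sizes from all small RNA counts and no TMM factors, 154 (7 higher, 147 lower) were called. Under that scale let-7c was at -0.31, let-7g at -0.82, let-7i at -1.44, Mir221 at -1.08, Mir143 at -1.09, Mir192 at -1.43, Mir27b at -1.57, Mir7-2/Mir7-1 at -1.73 and Mir669c at -0.40, while miR-122 stayed at 5.52. Library totals alone gave 98 (16 higher, 82 lower), with Mir7-2/Mir7-1 at -0.12. Leaving out each library in turn gave 57 (without PDGFR cells) to 83 (without PDGFR RNPs), over 1.5 times off for 1 of 8.

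**Figure D5:**
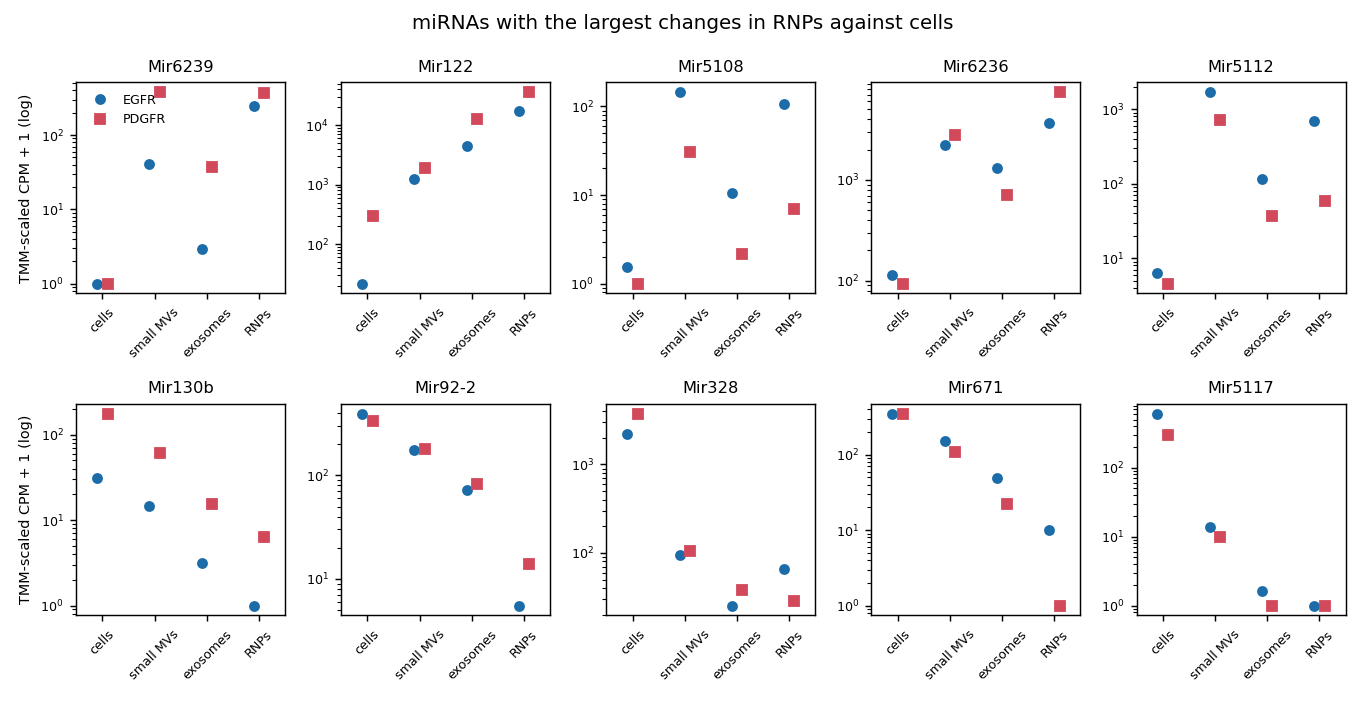
TMM-scaled CPM + 1 (log axis) of the 5 miRNAs with the largest rise (top) and the 5 with the largest fall (bottom) in RNPs against cells, with 1 point per library, circles for EGFR and squares for PDGFR. Mir122 counts were 151 and 1988 in cells and 11438 and 61100 in RNPs.

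Few miRNAs also passed the threshold between RNPs and exosomes, though 54 of 195 had an unadjusted p under 0.05, against 9.75 expected by chance. Mir6538 (6.04, SE 1.14, adjusted p = 0.0432), Mir6239 (5.15, SE 1.01, adjusted p = 0.0476), Mir5108 (3.02, SE 0.66, adjusted p = 0.0476), Mir6236 (2.45, SE 0.49, adjusted p = 0.0432) and Mir374b (2.15, SE 0.39, adjusted p = 0.0432) rose in RNPs. Mir92-2 (-3.01, SE 0.47, adjusted p = 0.0432), Mir351 (-2.84, SE 0.52, adjusted p = 0.0432), Mir92-1 (-2.62, SE 0.45, adjusted p = 0.0432), Mir99b (-2.37, SE 0.40, adjusted p = 0.0432) and Mir5099 (-2.21, SE 0.43, adjusted p = 0.0432) fell. Mir122 did not pass (1.75, SE 0.71, adjusted p = 0.176). edgeR called 13 of 195, 7 higher and 6 lower. DESeq2 called 30 (18 higher, 12 lower), library totals alone gave 5 (1 higher, 4 lower), and library sizes from all small RNA counts gave 127 (3 higher, 124 lower). The count was over 1.5 times off for 5 of 8 left-out libraries, from 0 (without EGFR small microvesicles) to 32 (without PDGFR RNPs).

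By this test the lines differed in 57 miRNAs, and those named first were chosen to have 1 direction in all 4 fractions. In the PDGFR line, Mir676 (7.91, SE 0.67, adjusted p = 0.000399), Mir224 (5.72, SE 0.44, adjusted p = 0.000391), Mir378d (5.31, SE 0.56, adjusted p = 0.000826), Mir214 (4.57, SE 0.61, adjusted p = 0.00186) and Mir129-2/Mir129-1 (3.73, SE 0.20, adjusted p = 0.000173) rose. Mir1964 (at least 2441-fold lower, adjusted p = 0.00126), Mir335 (-9.50, SE 0.74, adjusted p = 0.000391), Mir139 (-6.99, SE 0.75, adjusted p = 0.000826), Mir338 (-5.79, SE 0.49, adjusted p = 0.000399) and Mir204 (-5.17, SE 1.10, adjusted p = 0.0151) fell. Among neural miRNAs, Mir218-1/Mir218-2 rose (2.95, SE 0.29, adjusted p = 0.000756) and Mir9-2/Mir9-3 fell (-1.29, SE 0.24, adjusted p = 0.00858). Among glioma-associated miRNAs, Mir7-2/Mir7-1 rose (0.99, SE 0.17, adjusted p = 0.00601) and Mir221 fell (-1.11, SE 0.18, adjusted p = 0.00472). The p53-induced Mir34c fell (-2.38, SE 0.20, adjusted p = 0.000399), the mesenchymal Mir199a-1/Mir199a-2/Mir199b rose (1.68, SE 0.25, adjusted p = 0.00369), and Mir126a rose (2.09, SE 0.59, adjusted p = 0.0387). Mir3074-1/Mir24-2 (-1.03), Mir27b (-0.86) and Mir541 (-5.80) fell. edgeR called 57 of 195, 25 higher and 32 lower, against 52 (31 higher, 21 lower) with RLE size factors and 42 (24 higher, 18 lower) with library sizes from all small RNA counts. With 1 library left out, the count ran from 32 (without EGFR exosomes) to 61 (without PDGFR RNPs), over 1.5 times off for 4 of 8 libraries. No miRNA list passed the set test in any of the 6 comparisons, and copies of 1 miRNA at several loci cannot be told apart.

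The tRNA counts of RNPs came mostly from glycine and glutamate tRNAs. GlyCCC/GlyGCC rows held 40.9% and 58.4% of tRNA counts in RNPs, against 13.8% and 24.6% in cells. GluCTC rows held 34.5% and 34.5% in RNPs, against 8.4% and 42.4% in cells. Relative to other tRNAs, the unnamed repeat clusters 808 (at least 251-fold higher, adjusted p = 0.00627), 813 (at least 176-fold higher, adjusted p = 0.00882) and 829 (186-fold higher, counting interval 63.1 to 903, adjusted p = 0.00627) rose most. ThrCGT cluster 225 (-7.83, SE 1.57, adjusted p = 0.00698), MetCAT cluster 1120 (at least 25.4-fold lower, adjusted p = 0.0479) and ArgACG cluster 311 (-6.49, SE 1.47, adjusted p = 0.00796) fell most. edgeR called 41 of 98 tRNA rows, 23 higher and 18 lower. With library totals alone the count was 68 (4 higher, 64 lower), and with library sizes from all small RNA counts 11 (8 higher, 3 lower). tRNA genes of 1 isotype are near-identical, so a row stands for a group of copies.

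Single tRNA rows rose and fell in vesicles relative to other tRNAs. In small microvesicles, AlaTGC cluster 519 (6.04, SE 0.99, adjusted p = 0.00495) and the unnamed clusters 724 (7.20, SE 1.11, adjusted p = 0.00445) and 1013 (6.15, SE 1.65, adjusted p = 0.0456) rose. AlaTGC cluster 870 (-3.85, SE 0.88, adjusted p = 0.031), LeuCAA cluster 904 (-3.20, SE 0.88, adjusted p = 0.0477) and ValTAC cluster 661 (-3.16, SE 0.76, adjusted p = 0.031) fell. In exosomes, cluster 724 (7.33, SE 1.15, adjusted p = 0.00356), GluCTC cluster 835 (6.11, SE 1.23, adjusted p = 0.0112) and cluster 1013 (6.07, SE 1.66, adjusted p = 0.0338) rose. AlaTGC cluster 870 (at least 146-fold lower, adjusted p = 0.00348), LeuTAA cluster 1251 (at least 53.6-fold lower, adjusted p = 0.0379) and ThrCGT cluster 225 (at least 41.9-fold lower, adjusted p = 0.018) had 0 counts in both exosome libraries and fell. edgeR called 12 rows in small microvesicles (8 higher, 4 lower) and 25 in exosomes (8 higher, 17 lower). With RLE size factors the split was 17 (8 higher, 9 lower) in small microvesicles and 17 (9 higher, 8 lower) in exosomes. Library totals alone gave 15 (6 higher, 9 lower) and 29 (6 higher, 23 lower), and library sizes from all small RNA counts gave 3 (3 higher, 0 lower) and 48 (1 higher, 47 lower). Leaving out each library in turn gave 3 (without EGFR small microvesicles) to 29 (without EGFR exosomes), over 1.5 times off for 7 of 8. For exosomes the range was 4 (without PDGFR exosomes) to 35 (without EGFR RNPs).

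On the TMM scale, single glycine, glutamate and aspartate tRNA rows lay higher in RNPs than in exosomes. AspGTC cluster 853 (at least 25.9-fold higher, adjusted p = 0.0199), GlyCCC cluster 812 (4.97, SE 0.76, adjusted p = 0.00294) and GluCTC cluster 830 (4.91, SE 1.38, adjusted p = 0.0444) rose. ArgACG cluster 311 (-6.73, SE 1.49, adjusted p = 0.019), IleTAT cluster 376 (-6.25, SE 1.61, adjusted p = 0.0319) and the unnamed cluster 373 (-3.96, SE 0.76, adjusted p = 0.00969) fell. As shares of tRNA counts, the directions differed. AspGTC rows went from 0.229% in exosomes to 0.057% in RNPs in the EGFR line, and from 0.0341% to 0.0203% in the PDGFR line. GluCTC and GlyCCC rows held more in RNPs in the EGFR line and less in the PDGFR line, where GluCTC went from 50.8% to 34.5%. GlyCCC/GlyGCC rows held more in RNPs in both lines. edgeR called 15 of 98 rows, 12 higher and 3 lower. RLE size factors gave 11 (6 higher, 5 lower), library totals alone 27 (0 higher, 27 lower), and library sizes from all small RNA counts 45 (45 higher, 0 lower). The count was over 1.5 times off for 2 of 8 left-out libraries, from 0 (without PDGFR exosomes) to 25 (without PDGFR cells). Between exosomes and small microvesicles edgeR called 0 rows, with 16 at an unadjusted p under 0.05, and DESeq2 called 15 (9 higher, 6 lower). LeuCAG cluster 901 (4.72, SE 1.32, adjusted p = 0.12) and LeuTAA cluster 1251 (at least 17.6-fold lower, adjusted p = 0.209) had the largest values there. With 1 library left out, the count ran from 0 (without EGFR small microvesicles) to 8 (without EGFR RNPs), over 1.5 times off for 5 of 8 libraries.

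Some glutamate tRNA rows differed between the lines. In the PDGFR line, GluCTC cluster 824 (2.66, SE 0.34, adjusted p = 0.00153), GluTTC cluster 827 (4.37, SE 0.82, adjusted p = 0.0166) and the unnamed cluster 829 (4.79, SE 1.10, adjusted p = 0.0484) rose. GluCTC cluster 824 had 11278 counts in EGFR cells and 90621 in PDGFR cells. edgeR called 4 of 98 rows, 4 higher and 0 lower, and DESeq2 called 13 (10 higher, 3 lower). Library totals alone gave 32 (1 higher, 31 lower), and library sizes from all small RNA counts gave 0. Leaving out each library in turn gave 0 (without PDGFR exosomes) to 11 (without EGFR exosomes), over 1.5 times off for 8 of 8.

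Rny1 was more frequent in small microvesicles, exosomes and RNPs than in cells in 2 of 2 lines. Rny3 was more frequent in small microvesicles and less frequent in exosomes than in cells in 2 of 2 lines. In RNPs Rny3 was higher in the EGFR line, and its direction in the PDGFR line turned with the scale. Rny1 and Rny3 together made 3857 and 1267 CPM of small RNA counts in cells. They made 21933 and 18740 in small microvesicles, 38038 and 7250 in RNPs, and 4702 and 943 in exosomes. For the sum, RNPs thus held 9.86 and 5.72 times the value of cells, or 32.7 and 15.7 times relative to miRNA counts. Rny1 made 1774 and 417 CPM in cells, 16768 and 14427 in small microvesicles, 3797 and 824 in exosomes and 21769 and 6857 in RNPs. Rny3 made 2083 and 851 CPM in cells, 5165 and 4312 in small microvesicles, 905 and 119 in exosomes and 16270 and 394 in RNPs. In the PDGFR line Rny3 in RNPs was thus lower than in cells, but relative to miRNA counts it was higher, at 1242 against 976 CPM. With 1 library per line and fraction, no test was made.

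The lines shared fraction changes to different degrees by kind of RNA. Pearson's r between the lines' log2 ratios to cells was 0.241 in small microvesicles, 0.51 in exosomes and 0.551 in RNPs for long RNA genes. For miRNAs it was 0.854, 0.868 and 0.807, and for tRNA rows 0.691, 0.624 and 0.863. These values used 7021 genes, 171 miRNAs and 98 tRNA rows, which are not independent replicates. Long RNA counts without rRNA were spread over far more rows than miRNA counts. For these kinds, a difference in sharing cannot be told from counts per row. In the 3 comparisons of a fraction with cells the same cell libraries serve as reference. With a single library per line and fraction, the spread in every test was the difference between lines in how fractions changed.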

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

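The tests of this part were chosen after seeing the data, with predictions written before their results were seen. Small RNA clusters with no annotation, which no comparison used, held 20.5% of counts in EGFR and 17.5% in PDGFR small microvesicles, against 2.29% and 1.61% in cells, and were listed as a signal outside the main measurement. A few clusters holding the rise was 1 explanation, and its prediction was not met: the 5 largest held 21.4% and 48.6% of the class, a mean of 35.03%. This is a share of the class in small microvesicles and not of its rise over cells. In the PDGFR line 5 of 602 clusters held 48.6%, so a rise held by few clusters is not excluded there. Short reads placed by chance was the other, and its prediction was met: the 479 clusters higher in both lines had a median span of 22 nt against 26 nt for the other 123 of 602, a difference of -4 nt (95% interval -7 to -3). The span cannot tell short reads that match the genome by chance from a set of short RNA fragments made in vesicles. Which source the reads had was not tested.

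ERCC control RNAs held 4.3% of counts in PDGFR RNPs, against at most 0.0159% in any other library, a signal outside the main measurement. The following shares, taken without rRNA for long RNA, moved in opposite directions in the 2 lines relative to cells, and the differences were not tested. The ratio of exosomes to cells was 1.27 in the EGFR line and 0.749 in the PDGFR line for ribosomal protein mRNAs, and 0.663 and 0.0981 with rRNA kept in the total. For small structural RNAs it was 0.891 in the EGFR line and 5.07 in the PDGFR line, and 0.464 and 0.665 with rRNA kept. For snoRNAs and scaRNAs it was 0.239 in the EGFR line and 2.59 in the PDGFR line, and 0.124 and 0.339 with rRNA kept. In these 3 classes both lines were thus lower than cells once rRNA was kept, and the opposite directions rested on the total used. The ratio of small microvesicles to cells was 1.69 in the EGFR line and 0.468 in the PDGFR line for olfactory receptor genes, and 1.76 and 0.24 with rRNA kept, still opposite. By the reads recovered from the normalised table, 1 olfactory receptor gene held 37.7% of the family's reads in EGFR and 67.5% in PDGFR small microvesicles. In EGFR and PDGFR cells the highest gene held 6.32% and 6.13%, so single genes weigh on this ratio. For the sum of Rny1 and Rny3 the ratio of exosomes to cells was 1.22 in the EGFR line and 0.744 in the PDGFR line, as shares of small RNA counts. Each Y RNA alone went the same way in both lines. Rny1 was higher in exosomes than in cells (3797 against 1774 CPM in the EGFR line, 824 against 417 in the PDGFR line). Rny3 was lower (905 against 2083 and 119 against 851 CPM), so the opposite directions rested on the sum.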

How the results depend on the processing

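Counts of calls are named below by fraction against cells unless another pair is given. Comparisons not listed kept their count within 1.5 times. DESeq2 gave genes 236 for small microvesicles, 689 for exosomes, 1270 for RNPs, 154 for exosomes to small microvesicles, 905 for RNPs to exosomes, 683 for the lines, and miRNAs 43 for exosomes to small microvesicles, 30 for RNPs to exosomes, tRNAs 29 for small microvesicles, 44 for exosomes, 15 for exosomes to small microvesicles, 29 for RNPs to exosomes, 13 for the lines. RLE size factors gave genes 0 for small microvesicles. Library totals alone gave genes 11 for exosomes, 2212 for RNPs, and miRNAs 5 for RNPs to exosomes, tRNAs 68 for RNPs, 1 for exosomes to small microvesicles, 27 for RNPs to exosomes, 32 for the lines. No low-count filter gave genes 63 for small microvesicles, 166 for exosomes, 58 for exosomes to small microvesicles, 253 for RNPs to exosomes, 315 for the lines, tRNAs 7 for small microvesicles, 11 for exosomes. A mean of at least 10 CPM gave genes 0 for small microvesicles, 0 for exosomes, 248 for RNPs, 22 for the lines, tRNAs 7 for small microvesicles, 11 for exosomes. Keeping rRNA gave genes 31 for small microvesicles, 132 for exosomes, 25 for exosomes to small microvesicles, 190 for RNPs to exosomes, 254 for the lines. Leaving line (or fraction, for the lines) out of the model gave genes 0 for small microvesicles, 0 for exosomes, 0 for RNPs, 0 for the lines, and miRNAs 13 for small microvesicles, 16 for exosomes, 29 for RNPs, 0 for exosomes to small microvesicles, 0 for RNPs to exosomes, 15 for the lines, tRNAs 4 for small microvesicles, 11 for exosomes, 26 for RNPs, 0 for RNPs to exosomes, 0 for the lines. Library sizes from all small RNA clusters gave miRNAs 154 for RNPs, 127 for RNPs to exosomes, tRNAs 3 for small microvesicles, 48 for exosomes, 11 for RNPs, 55 for exosomes to small microvesicles, 45 for RNPs to exosomes, 0 for the lines. Extracellular fractions alone gave tRNAs 9 for the lines. Without both RNP libraries, an alternative chosen after seeing the data, the counts were genes 0 for small microvesicles, 0 for exosomes, 37 for the lines, and miRNAs 35 for exosomes to small microvesicles, tRNAs 3 for small microvesicles, 12 for exosomes, 0 for the lines. Without the rRNA-like loci, also chosen after seeing the data, they were genes 0 for small microvesicles, 1 for exosomes, 70 for the lines. In the 10 CPM setting fewer genes were tested. For the other settings the cause was not tested. The reads recovered from the normalised table changed no count by over 1.5 times. With an estimated correlation, 0 lists of genes passed in all 6 comparisons. Median rho of long RNA libraries was 0.671, and 0.36 at a mean of at least 10 CPM. The Y RNA ratios of RNPs to cells of 9.86 and 5.72 were 32.7 and 15.7 relative to miRNA counts, since miRNAs held a smaller share in RNPs. Of 48 class directions, 22 were higher than cells, and 12 with rRNA kept in the total.

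Direction reversed for 21 values. Without PDGFR RNPs, Pecam1 in RNPs was at -2.05, the lowest of its range up to 10.36 (without EGFR RNPs). With library totals alone, RNP values were Mir7-2/Mir7-1 -0.12, Mir34c -0.20. Library sizes from all small RNA clusters count all small RNA instead of miRNAs alone, and were used without TMM factors. With them, small microvesicle values were let-7f-2 -0.14, Mir7-2/Mir7-1 -0.19, Mir221 -0.18. RNP values were let-7c -0.31, let-7g -0.82, let-7i -1.44, Mir221 -1.08, Mir7-2/Mir7-1 -1.73, Mir143 -1.09, Mir192 -1.43, Mir34c -1.80, Mir199a-1/Mir199a-2/Mir199b -1.58, Mir27b -1.57, Mir669c -0.40, and for RNPs against exosomes let-7c -1.47, let-7b -0.91, Mir29a -1.99, Mir27b -1.87. Leaving out 1 library at a time gave these ranges. For genes they were 11 to 147 for small microvesicles, 9 to 334 for exosomes, 209 to 1056 for RNPs, 2 to 110 for exosomes to small microvesicles, 13 to 448 for RNPs to exosomes, 63 to 394 for the lines. For miRNAs they were 22 to 84 for small microvesicles, 35 to 101 for exosomes, 57 to 83 for RNPs, 0 to 38 for exosomes to small microvesicles, 0 to 32 for RNPs to exosomes, 32 to 61 for the lines. For tRNAs they were 3 to 29 for small microvesicles, 4 to 35 for exosomes, 32 to 54 for RNPs, 0 to 8 for exosomes to small microvesicles, 0 to 25 for RNPs to exosomes, 0 to 11 for the lines. A lone sample then stands for its line, with the spread pooled over fractions. Depth limits the long RNA tests most in RNPs, where a gene absent in RNPs can be shown to fall only if cells held many counts.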

Other observations

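The tests of this part were chosen after seeing the data, except those said to be predicted before. Genes near 0 in cells rose in RNPs, olfactory receptor genes and Pou1f1 among them. Genomic DNA cannot be told from this measure: olfactory receptor reads touched 112 and 110 of 1409 genes, at most 0.104 of what an even spread would touch, but EGFR and PDGFR cells also lay low (0.193 and 0.352). The prediction of random amplification, written before, was not met. Of 5561 genes under 1 CPM in cells, 105 reached 10 reads in both RNP libraries. Independent lists gave 9.06, a ratio of 11.6 (95% interval 9.48 to 14). Such lists take all genes as equally likely to be read, so this ratio cannot exclude random amplification. The prediction of composition scaling was not met, as 75.3% of the genes called higher stayed so with library totals alone. Both scales are relative to the other genes without rRNA, so other effects of scaling are not excluded. Genomic DNA, random amplification, mapping of repeats and RNA of the serum stay open.

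miR-122 was higher outside cells in both lines. Serum carried into the medium, predicted before, cannot be told: the other 2 measured members of the list, Mir126a (-0.89, adjusted p = 0.397) and Mir16-1 (-0.57, adjusted p = 0.259), had a median of -0.73 in RNPs and met the prediction against serum there. They went the other way in exosomes (0.99 and 0.45), and Mir126a also in small microvesicles (1.93), none past the threshold. With 2 members and no profile of the serum itself this is not decisive, and serum rich in miR-122 alone could give the same result. Abundant miRNAs setting the scale was not borne out, as miR-122 stayed at 5.52 with library sizes from all small RNA counts.

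Further hypotheses gave no clear answer. p53-induced miRNAs had a median log2 fold change of -0.27 between the lines, where 1 of 5 fell (Mir34c) and adjusted p = 0.743, so a loss of p53 lowering them cannot be told. The criteria for this test and for genomic DNA were rewritten after their results were seen. The prediction that longer transcripts are lower in every extracellular library, written before, was not met. Rho of length with the change was -0.214 in PDGFR small microvesicles, 0.282 in EGFR exosomes and -0.0225 to 0.111 in the other extracellular libraries. It was taken over 7390 genes, which are not independent replicates. The opposite prediction was not met either, because of PDGFR small microvesicles, so an effect in single libraries is not excluded. Grouping of libraries by line was tested with splits that part each fraction, and 8 splits are too few to tell. The real split gave 128 genes, 57 miRNAs and 4 tRNAs, was 1 of 8 in each, and the highest other split gave 0.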
